A study of Mus musculus with 6 samples.

How the data were processed

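RNA sequencing was done on CD31-selected cells from the lungs of mouse pups at postnatal day 5, in 3 control and 3 mutant libraries. Per the labels' protocols, lungs were digested with collagenase and dispase, cells were pulled down with magnetic beads coated with CD31 antibody, and libraries were made from polyadenylated RNA with a TruSeq RNA v2 kit. The labels describe independent biological samples in a sentence that calls the mice HHTf/f and HHTiECKO, while the rest of the protocol names floxed Smad4 mice with and without Cdh5-CreERT2, and the labels do not explain this difference. The groups were taken from the sample titles and the genotype labels, which call the controls wildtype where the protocol gives floxed alleles without Cre.

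The deposited values are raw gene counts, as whole numbers per gene symbol and library, with no normalization. The authors deposited these counts both per library and as a table of the series, and the number of values that differed between the 2 forms was 0. Per the submitters' processing notes the genome build was mm10, and DESeq2 is named there with no version or role. The aligner, the counting tool and the annotation are not given in the sources used here, nor is the use of strand in counting, so reads of overlapping or antisense genes may not be told apart. The deposited counts hold 24951 genes, of which 19588 had at least 1 count. Reads with no feature made up 53.9% to 58.2% of each library's total and ambiguous reads 0.288% to 0.366%. Both were left out of library sizes and tests. Per library, the 95% exact binomial (Clopper-Pearson) interval of the no-feature share was at most ± 0.0166 percentage points, which covers counting error only. Assigned reads came to 14093564 to 21113926 per library, so that 3 counts, taken as the floor, correspond to 0.142 to 0.213 CPM. The number of mitochondrially encoded genes among the features was 0.

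Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group design, which left 14934, and libraries were scaled by TMM factors. Dispersions and quasi-likelihood fits used the robust option, and the test was the two-sided quasi-likelihood F test of mutant against control with all 6 libraries and no covariate. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of F. CPM values used the TMM-scaled library sizes. Replicates of a group were compared with a chi-square test of their counts, and every pair differed by more than sampling noise, with a chi-square per degree of freedom of at least 12.9.

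Gene lists were fixed before the data were examined: 23 pathway and endothelial lists and 13 lists of markers of other cell types. Of 660 list symbols, 657 matched a gene in the counts, 2 of them through an older symbol. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 36 lists. The estimated form of camera also has far fewer degrees of freedom, set by the libraries and not by the genes. Counts of called members are given over all genes and adjusted over the list alone.

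The genes that could be named were set by a rule written before the data were examined. It took Smad4, and among called genes with a mean log2 CPM of at least 2 and no overlap between groups the 12 with the largest increase and the 12 with the largest decrease, leaving out unnamed gene models, immune receptor segments, mitochondrially encoded genes and a fixed list for the check of sex (Xist, Tsix and 4 Y-linked genes). Other genes of the X chromosome could be named. It also took from each list up to 4 called members with the smallest p (or, where fewer than 2 were called, the 2 with the smallest p), members of the retinoid lists, a fixed set of SMAD and angiopoietin pathway genes, and the most abundant markers of other cell types. The text prints part of the genes this rule allows and says where a gene outside it was chosen after its values were seen. Coordinates and gene identifiers are those of GENCODE M21 on GRCm38, the same assembly as mm10, matched by symbol.

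The fitting functions were tested on simulated data drawn from the means, dispersions and library sizes of these libraries, with 200 genes changed by known folds. In that simulated comparison of mutant against control, over 14822 genes, edgeR recovered 29.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 86.4% of those changed 4-fold, with 11 false calls. On the same simulated data DESeq2 recovered 40.3%, 71.6% and 87.9% with 32 false calls, and limma-voom 26.9%, 64.2% and 89.4% with 10. With no gene changed edgeR made 1 false call among 14812 genes. Camera called 0 of 36 lists there and 1 list when the cell division genes were raised 1.5-fold. The simulated genes were drawn independently of each other, so these counts do not show how camera behaves when the genes of a list are correlated.

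The alternatives were RLE and upper-quartile factors, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, sex as a covariate, haemoglobin and ribosomal protein genes left out, and each library left out in turn. Sex was read from Xist and 4 Y-linked genes, and each group held 1 male and 2 female libraries. A fit on the female libraries was added after the data were seen. Xist stood at 1.09, 1328 and 1189.5 CPM in control replicates 1, 2 and 3 and at 1.19, 566 and 972 CPM in mutant replicates 1, 2 and 3, before TMM scaling. The series table could not act as another input, since its values were those of the single files.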

Results

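Lung endothelial cells were profiled by RNA sequencing in mouse pups at postnatal day 5. Smad4 encodes the SMAD partner shared by the BMP and TGF-beta branches of the pathway. The mutant pups carried 2 floxed Smad4 alleles and the Cdh5-CreERT2 transgene, a tamoxifen-inducible Cre recombinase made in endothelial cells. The labels do not give the dose or day of tamoxifen, so the time from deletion to sampling is not known here. The control pups carried the floxed alleles without Cre, so no group of the series has Cre together with intact Smad4. Cells were taken from digested lungs with beads coated with an antibody to CD31, a surface protein of endothelial cells, and polyadenylated RNA was sequenced. There were 3 control and 3 mutant libraries, which the labels describe as independent biological samples. The names of all 6 libraries in the deposited table share a tag that the labels do not explain, so it is not known here whether the pups came from the same litter. Reads assigned to genes came to 21113926, 14093564 and 20874393 in control replicates 1, 2 and 3, and to 18543717, 16041786 and 20172318 in mutant replicates 1, 2 and 3. The study title names retinoic acid signaling in endothelial cells and pulmonary arteriovenous malformations, which are direct connections between arteries and veins of the lung. The comparison asks which transcripts differ in lung endothelial cells after endothelial deletion of Smad4.

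Smad4 (ENSMUSG00000024515.13) lies on chromosome 18 of GRCm38, from 73639009 to 73703780 on the minus strand. Its level was 188, 177 and 181 CPM, counts scaled by library size, in control replicates 1, 2 and 3, and 88.8, 72.9 and 94.2 CPM in mutant replicates 1, 2 and 3. The group means were 182 ± 5.74 CPM in control and 85.3 ± 11.1 CPM in mutant libraries (SD, n = 3 each). The log2 fold change was -1.09 with an SE of 0.10 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000604), a level 2.13-fold lower in the mutants. The labels do not name the floxed exons, so counts over the whole gene can include reads from the part of the transcript that remains after recombination. How complete the deletion was, and in what share of the cells, cannot be read from these counts.

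In the mutant libraries, genes of the interferon response, the tip cell gene Apln and the basement membrane gene Lamb1 were higher, while the capillary gene Sema3c, the chemokine gene Cxcl12, the BMP receptor gene Bmpr2 and the retinoic acid-degrading enzyme gene Cyp26b1 were lower. Rsad2, an antiviral interferon-induced gene, went from 2.61 ± 0.0932 to 53.6 ± 23.3 CPM, 20.6-fold higher, and Apln, the ligand of the apelin receptor, from 212 ± 21.0 to 687 ± 48.4 CPM, 3.25-fold higher (SD, n = 3 each). Sema3c, a secreted semaphorin, went from 480.4 ± 15.4 to 152 ± 18.1 CPM, 3.16-fold lower, and Cxcl12 from 501 ± 65.5 to 128 ± 43.2 CPM, 3.92-fold lower. In all, 488 of 14934 tested genes changed at an adjusted p under 0.05, with 288 higher and 200 lower. Of these, 135 rose and 49 fell by at least 2-fold. In each of the 488 genes the 3 mutant libraries did not overlap the 3 control libraries. The calls rest on the same values, so this is not separate support for them. Among all tested genes 20.6% had no overlap, where chance gives 10%. DESeq2 called 747 genes, and the count fell to 211 without mutant replicate 2, 293 without control replicate 2 and 325 without control replicate 3. Without mutant replicate 2 the count of genes changed at least 2-fold was 103, against 184.

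**Figure D1:**
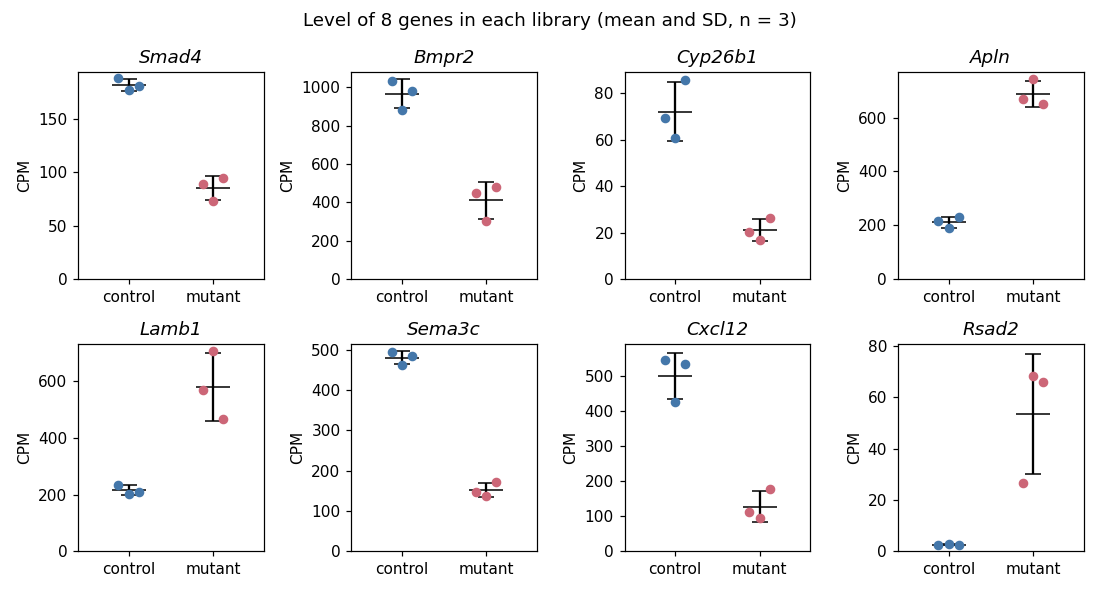
Level of 8 genes in CPM in each control and mutant library, with each point a library and each bar the group mean with its SD (n = 3). The 3 mutant libraries lie at 72.9 to 94.2 CPM for Smad4 and the 3 control libraries at 177 to 188 CPM, and the groups do not overlap for any of the 8 genes.

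The 12 genes with the largest increase under the naming rule were Apol9b, with a log2 fold change of 4.49, Rsad2 with 4.36, Ifit1 with 4.31, Ifi44 with 3.71, Oasl1 with 3.56, Oas3 with 3.45, Oas1a with 3.44, Isg15 with 3.30, Irf7 with 3.01, Clca2 with 2.98, Eda2r with 2.69 and Oasl2 with 2.66. Of these, 8 are on the interferon response list, and Apol9b, Oas3, Clca2 and Eda2r, an ectodysplasin receptor gene, are not. Clca2 went from 2.22 ± 0.357 to 17.4 ± 3.55 CPM (SE 0.21, adjusted p = 0.00014). The 12 genes with the largest decrease were Slc26a10, with a log2 fold change of -2.69, Ntrk2 with -2.48, Hcn4 with -2.22, Lamc3 with -2.03, Cxcl12 with -1.97, Hpgd with -1.94, Cyp26b1 with -1.76, Esr2 with -1.76, Wif1 with -1.68, Sema3c with -1.66, Begain with -1.51 and Rasgef1a with -1.51. Hpgd, the main enzyme of prostaglandin breakdown, went from 449.7 ± 56.4 to 117 ± 56.7 CPM (SE 0.35, adjusted p = 0.0463), and Wif1, a secreted Wnt inhibitor, from 161 ± 36.8 to 50.1 ± 11.7 CPM (SE 0.22, adjusted p = 0.00771). Ntrk2, the receptor gene for brain-derived neurotrophic factor, went from 48.5 ± 10.6 to 8.66 ± 2.75 CPM. Apol9b, Ifit1, Oas3, Oas1a, Hcn4, Hpgd and Esr2 lost their call in at least 4 of the 6 fits that left out a library, without control replicates 1 and 2 in every case. Those of Apol9b and Ifit1 were kept only without mutant replicate 1, those of Oas3 and Oas1a without mutant replicate 1 or 3, that of Hcn4 only without control replicate 3, that of Hpgd without mutant replicate 2 or 3 and that of Esr2 only without mutant replicate 3. Without control replicate 1 the adjusted p was 0.237 for Apol9b, 0.115 for Ifit1, 0.168 for Oas3, 0.190 for Oas1a, 0.0857 for Hcn4, 0.195 for Hpgd, 0.0683 for Esr2 and 0.0501 for Cxcl12. With sex as a covariate the calls of Hpgd and Ifit1 ended (adjusted p = 0.138 and 0.0893), and with upper-quartile factors those of Hpgd and Apol9b (0.0563 and 0.0556). With no low-count filter those of Apol9b, Ifit1, Oas3, Oas1a, Hcn4 and Hpgd ended (0.179, 0.0836, 0.139, 0.126, 0.0581 and 0.164), and with limma-voom those of Apol9b, Ifit1, Oas3, Oas1a and Hcn4 (0.283, 0.0860, 0.172, 0.179 and 0.0716).

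Of the 24 interferon response genes, 19 rose, 0 fell and 5 did not pass the test, and 24 rose when adjusted over the list alone. The 19 became 10, 12 and 8 without control replicates 1, 2 and 3 and 12 without mutant replicate 2. The list median was 2.60 on the log2 scale, and camera placed it above the other genes at the preset correlation (adjusted p = 6.23e-77), with adjusted p = 0.171 with an estimated correlation. Fry called the list (adjusted p = 0.0445). Rtp4, with the smallest p of the list, went from 21.4 ± 2.01 to 94.8 ± 17.1 CPM, a log2 fold change of 2.15 with an SE of 0.14 (adjusted p = 0.000139). Ifi44 went from 9.46 ± 1.02 to 124 ± 48.9 CPM and Oasl2 from 35.0 ± 4.34 to 220.4 ± 71.4 CPM. The increase differed between mutant libraries, and Rsad2 stood at 26.7, 68.2 and 66.0 CPM in mutant replicates 1, 2 and 3. The call of Rsad2 ended without control replicate 3 (adjusted p = 0.0540), as did those of Isg15 (0.0601), Oasl1 (0.0910) and Irf7 (0.119). Without control replicate 1 the calls of Isg15, Oasl1 and Irf7 ended (adjusted p = 0.0565, 0.0592 and 0.125), and without control replicate 2 that of Irf7 (0.0582), which also ended with no low-count filter (0.0638). Values of the Oas, Oasl, Apol9 and Ifit genes are uncertain as single genes, since they belong to families of similar sequence between which reads can be split. The 19 tested macrophage and monocyte, 12 neutrophil and 12 lymphocyte markers had medians of 0.10, 0.15 and -0.02 on the log2 scale, with 0 of them called by edgeR and 6 of the 43 at an unadjusted p under 0.05. DESeq2 called 2 of them and limma-voom 0. Without mutant replicate 1 edgeR called 3 macrophage markers higher, and without mutant replicate 2 it called 1 lymphocyte marker higher. Without control replicate 2 camera at the preset correlation called the neutrophil list upward, with a median of 0.37 (adjusted p = 0.0195). With all 6 libraries that list had camera adjusted p = 0.558 at the preset correlation and 0.972 at an estimated correlation of 0.65.

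**Figure D2:**
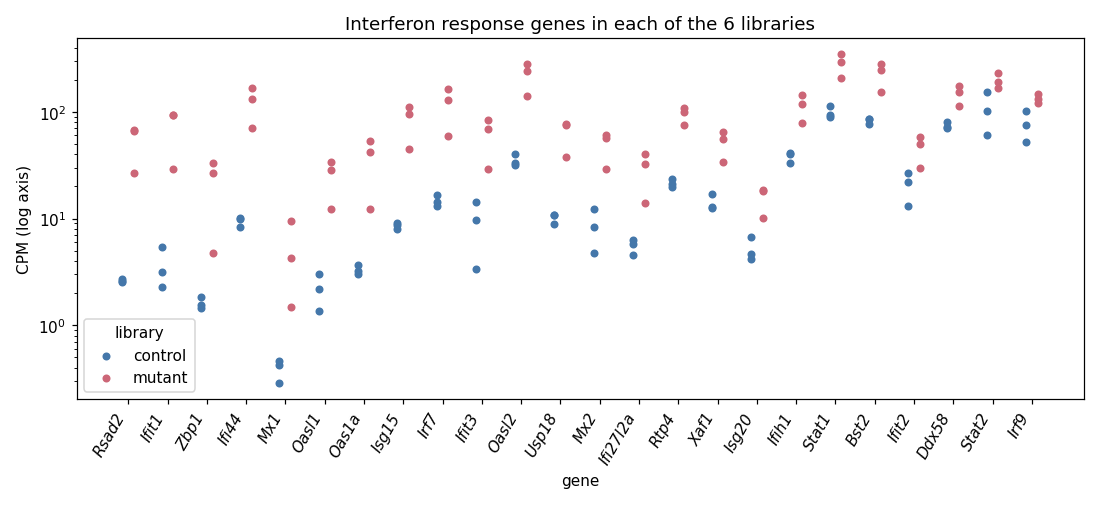
CPM on a log axis of each of the 24 interferon response genes in the 3 control and 3 mutant libraries, each point a library. Of the 24 genes, 19 rose, and the mutant libraries of Rsad2 lie between 26.7 and 68.2 CPM.

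Markers of the general capillary cells of the lung were lower. Of 18 tested markers, 9 fell, 1 rose and 8 did not pass, and adjusted over the list alone 11 fell and 2 rose. Without mutant replicate 2, 6 fell and 0 rose. The list median was -0.42 on the log2 scale (camera adjusted p = 3.85e-16 at the preset correlation, adjusted p = 0.171 with an estimated correlation, fry adjusted p = 0.0348). Scn7a, a sodium channel gene, went from 2467 ± 208 to 889.8 ± 196 CPM, a log2 fold change of -1.47 with an SE of 0.16 (adjusted p = 0.00224). Sema3c, on chromosome 5 from 17574281 to 17730268, had a log2 fold change of -1.66 with an SE of 0.10 (adjusted p = 5.35e-05). The fatty acid transporter gene Cd36 and the phospholipase gene Plcb1 each fell by 0.94 on the log2 scale. The marker that rose was Gpihbp1, the capillary anchor of lipoprotein lipase, named here after its values were seen, with a log2 fold change of 0.54. Its call ended without control replicate 2 (adjusted p = 0.0503) or mutant replicate 2 (0.0533). Of 20 markers of aerocytes, the other capillary cell of the alveolus, 1 rose, 3 fell and 16 did not pass, and adjusted over the list alone 1 rose and 7 fell. Without mutant replicate 1 or 2, 1 rose and 1 fell. Apln, on chromosome X from 48025146 to 48034853, was the aerocyte marker that rose, while Clec1a fell by 0.59 and Fibin fell by 0.83 on the log2 scale. The call of Fibin ended without mutant replicate 1 (adjusted p = 0.0520) or 2 (0.0963). This list had a median of -0.25 and did not pass camera (adjusted p = 0.0631). Camera at the preset correlation called it downward with limma-voom (adjusted p = 0.00285), with no low-count filter (0.0487) and without control replicate 2 (0.000345). With all 6 libraries its camera adjusted p was 0.889 at an estimated correlation of 0.28, and its fry adjusted p was 0.410.

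Of 29 arterial markers, 2 rose, 5 fell and 22 did not pass, and adjusted over the list alone 2 rose and 13 fell. Without control replicate 1, 2 or 3 or mutant replicate 2, 0 rose and 3 fell, without mutant replicate 1, 0 rose and 4 fell, and with sex as a covariate 1 rose and 3 fell. The median was -0.19 (camera adjusted p = 9.39e-06 at the preset correlation, adjusted p = 0.276 with an estimated correlation, fry adjusted p = 0.0445). Pcsk5, a proprotein convertase gene, went from 219 ± 22.4 to 93.2 ± 10.1 CPM, and Gja4, which encodes a gap junction protein of arteries, from 149 ± 5.01 to 79.1 ± 6.36 CPM. Their log2 fold changes were -1.23 and -0.91 (SE 0.11 and 0.09). Unc5b rose by 0.48 on the log2 scale, a call kept only without mutant replicate 3 among the 6 fits without a library (adjusted p up to 0.112, without mutant replicate 2). Of 25 shear stress and quiescence genes, 0 rose, 3 fell and 22 did not pass, and adjusted over the list alone 1 rose and 8 fell, with a median of -0.17 (camera adjusted p = 0.00271 at the preset correlation, adjusted p = 0.298 with an estimated correlation, fry adjusted p = 0.0457). The count of 3 became 1 without mutant replicate 2, 6 in DESeq2 and 5 with the replicate block. The 3 that fell were Gja4, Heg1 and the angiopoietin receptor gene Tek, which had log2 fold changes of -0.53 for Heg1 and -0.50 for Tek. The calls of Heg1 and Tek ended without mutant replicate 2 (adjusted p = 0.0664 and 0.0760), and that of Tek also without control replicate 3 (0.0540). Klf2, a flow-induced transcription factor gene on this list, stood at 175 ± 14.3 and 180 ± 12.4 CPM (adjusted p = 0.908).

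Some genes of tip cells and angiogenic activation were higher. Of 28 tested, 9 rose, 1 fell and 18 did not pass, and adjusted over the list alone 12 rose and 1 fell, with a median of 0.23 (camera adjusted p = 2.34e-12 at the preset correlation, adjusted p = 0.276 with an estimated correlation, fry adjusted p = 0.0445). The counts became 5 higher and 1 lower without control replicate 1, 5 and 0 without control replicate 2, and 4 and 0 without control replicate 3, mutant replicate 1 or mutant replicate 2. Trp53i11, also counted among the p53 targets given below, went from 115 ± 5.77 to 417 ± 60.9 CPM. Its log2 fold change was 1.86 with an SE of 0.11 (adjusted p = 5.35e-05). Apln had a log2 fold change of 1.70 with an SE of 0.10 at the same adjusted p, and Igfbp3 one of 2.40 with an SE of 0.27 (adjusted p = 0.00437). Angpt2, the angiopoietin that can oppose Tek signaling, rose from 24.8 ± 2.11 to 39.3 ± 6.11 CPM, a log2 fold change of 0.66 (adjusted p = 0.0227), with the call ended without control replicate 2 or 3 or mutant replicate 1 or 2 (0.0649, 0.0733, 0.0695 and 0.114). Kdr, which encodes VEGF receptor 2, stood at 1454 ± 117 and 1294 ± 26.3 CPM (adjusted p = 0.415). Of 16 basement membrane genes, 4 rose, 0 fell and 12 did not pass, and adjusted over the list alone 10 rose and 2 fell, with a median of 0.28 (camera adjusted p = 5.71e-08 at the preset correlation, adjusted p = 0.460 with an estimated correlation, fry adjusted p = 0.0892). Those that rose were the laminin genes Lama4 and Lamb1, with log2 fold changes of 1.38 and 1.42, and the collagen genes Col15a1 and Col4a1, with 1.01 and 0.43. The call of Col4a1 was kept only without mutant replicate 3 among the fits without a library, with an adjusted p of up to 0.120, without mutant replicate 2. Lamc3, a laminin gene outside this list, fell. Fibroblasts and pericytes are also known to make basement membrane, and among the mutants their marker lists and this list stood highest in replicate 2 and lowest in replicate 3. List medians of log2 CPM relative to the control mean were 0.30, 0.39 and 0.13 for basement membrane genes in mutant replicates 1, 2 and 3, 0.22, 0.38 and -0.076 for fibroblast markers, and 0.24, 0.52 and -0.028 for smooth muscle and pericyte markers. In control replicates 1, 2 and 3 they were 0.033, -0.055 and 0.011 for basement membrane genes, 0.13, 0.19 and -0.33 for fibroblast markers, and 0.17, 0.14 and -0.37 for smooth muscle and pericyte markers. The tip cell list had the same order among the mutants, with 0.27, 0.42 and 0.18 in mutant replicates 1, 2 and 3. In control replicates 1, 2 and 3 it stood at -0.021, 0.034 and 0.073.

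**Figure D3:**
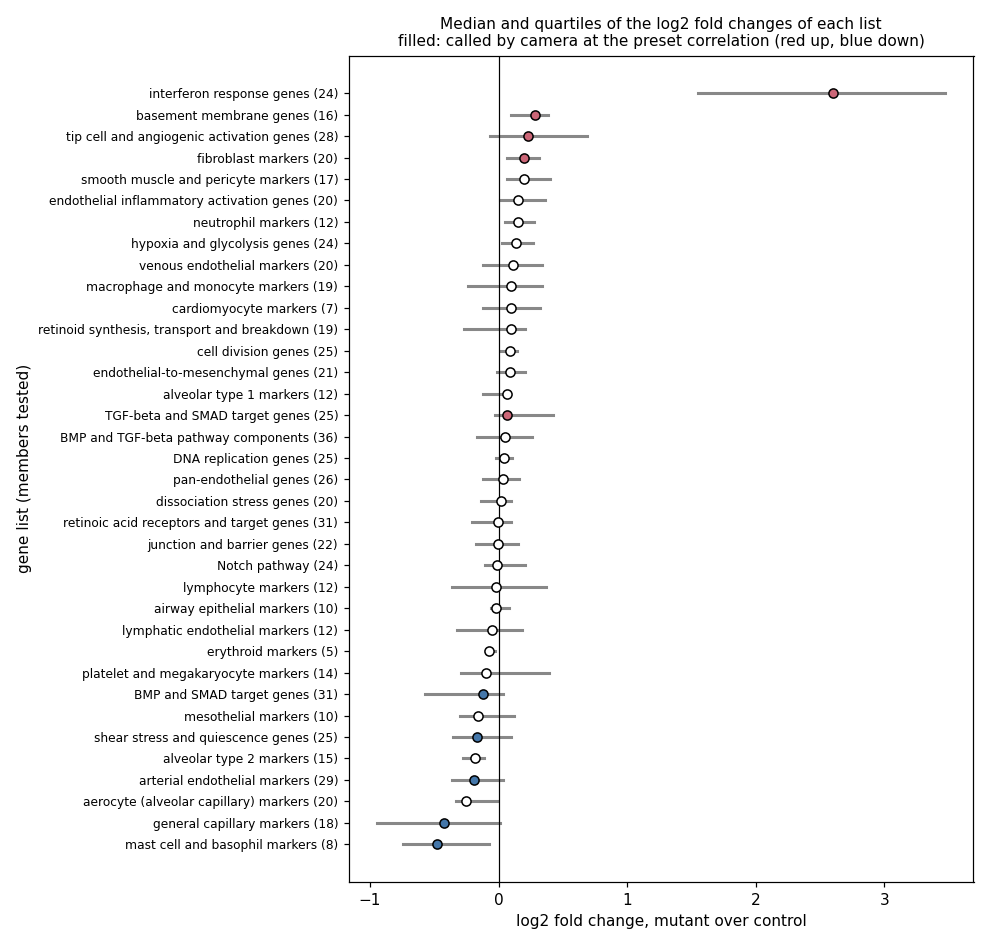
Median log2 fold change, mutant over control, of each of the 36 gene lists, with bars from the lower to the upper quartile of its tested members. Filled points mark the 10 lists called by camera at the preset correlation, with interferon response genes at 2.60 and general capillary markers at -0.42.

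Pathway components and targets of SMAD signaling moved in both directions. Of 36 components of the BMP and TGF-beta pathways, 5 rose, 3 fell and 28 did not pass, and adjusted over the list alone 6 rose and 6 fell. This list did not pass camera at the preset correlation (adjusted p = 0.292), and passed upward without mutant replicate 3 (0.0415). With all 6 libraries its camera adjusted p was 0.889 with an estimated correlation. Bmpr2, the BMP type II receptor gene on chromosome 1 from 59763400 to 59879014, went from 968 ± 76.5 to 411 ± 95.6 CPM, a log2 fold change of -1.24 with an SE of 0.17 (adjusted p = 0.00524). Acvrl1, which encodes the receptor ALK1, went from 970.3 ± 80.6 to 706 ± 23.2 CPM (log2 fold change -0.46, adjusted p = 0.0175), a call that ended without control replicate 3, mutant replicate 1 or mutant replicate 2 (0.0736, 0.0793 and 0.103). Eng, the co-receptor gene endoglin, stood at 915 ± 63.7 and 935 ± 29.6 CPM (adjusted p = 0.904). Smad1 rose from 56.1 ± 1.80 to 127 ± 11.2 CPM, and the ligand genes Inhbb and Bmp7 had log2 fold changes of 1.77 and 2.07. Of 31 BMP and SMAD target genes, 1 rose, 6 fell and 24 did not pass, and adjusted over the list alone 1 rose and 10 fell. Without mutant replicate 2, 1 rose and 3 fell. The median was -0.12 (camera adjusted p = 9.62e-05 at the preset correlation, adjusted p = 0.276 with an estimated correlation, fry adjusted p = 0.0445). The taurine transporter gene Slc6a6, Gja4, the kinase gene Sgk1 and Id2 fell by 1.03, 0.91, 0.64 and 0.58 on the log2 scale, and Bambi, a pseudoreceptor of the pathway, rose by 1.12. The call of Id2 ended without control replicate 2 (adjusted p = 0.0514) or mutant replicate 2 (0.0538). The other fixed readouts did not pass, with log2 fold changes of -0.19 for Id1, -0.14 for Id3, -0.57 for Smad6, -0.23 for Smad7 and -0.28 for Smad9 (adjusted p = 0.564, 0.579, 0.0656, 0.233 and 0.509). Smad6 passed in DESeq2 (adjusted p = 0.00423), with no low-count filter (0.0447), without control replicate 2 (0.0381) and without mutant replicate 3 (0.0262). Of 25 TGF-beta and SMAD target genes, 3 rose, 0 fell and 22 did not pass, and adjusted over the list alone 6 rose. The count of 3 became 1 without control replicate 2 or 3 or mutant replicate 1 or 2, 5 without mutant replicate 3, and 6 in DESeq2 and with no low-count filter. The median was 0.06 (camera adjusted p = 0.0235 at the preset correlation, adjusted p = 0.889 with an estimated correlation, fry adjusted p = 0.397), and the 3 genes were Ldlrad4 with a log2 fold change of 0.67, Pmepa1 with 0.61 and Col4a1 with 0.43. Pmepa1 kept its call without control replicate 1 or mutant replicate 3 (adjusted p up to 0.119 in the other fits, without mutant replicate 2). This list lost its call without control replicate 3, mutant replicate 1 or mutant replicate 2 (camera adjusted p = 0.107, 0.180 and 0.131), with a median of -0.03 in the last, and also in the female libraries (0.203). The fibroblast list lost its call without the same 3 libraries. List medians relative to the control mean were 0.16, 0.36 and -0.10 for the TGF-beta and SMAD targets in mutant replicates 1, 2 and 3, beside 0.22, 0.38 and -0.076 for fibroblast and 0.24, 0.52 and -0.028 for smooth muscle and pericyte markers. In control replicates 1, 2 and 3 those of the targets were 0.036, 0.059 and -0.032. Of the 25 targets 3 are also on the fibroblast or the smooth muscle and pericyte list (Acta2, Col1a1 and Tagln, named after their values were seen), and these did not pass (adjusted p = 0.788, 0.932 and 0.896).

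The 2 retinoid lists did not pass camera (adjusted p = 0.391 for synthesis, transport and breakdown and 0.312 for receptors and targets). Of 19 genes of retinoid synthesis, transport and breakdown, 0 rose, 1 fell and 18 did not pass, with the same counts when adjusted over the list alone. The median of this list was 0.09 and its mean -0.11, and the test pointed downward. The gene that fell was Cyp26b1, which encodes an enzyme that degrades retinoic acid and lies on chromosome 6 from 84571414 to 84593908. It went from 71.9 ± 12.7 to 21.2 ± 4.62 CPM, a log2 fold change of -1.76 with an SE of 0.18 (adjusted p = 0.00124). The synthesis enzyme gene Aldh1a1 stood at 45.5 ± 3.31 and 44.3 ± 5.74 CPM (adjusted p = 0.922), and Dhrs3 at 53.7 ± 3.77 and 45.9 ± 0.571 CPM (adjusted p = 0.306). Of 31 retinoic acid receptors and target genes, 1 rose, 3 fell and 27 did not pass, again with the same counts when adjusted over the list alone. Each fit without a library called 1 or 2 of these 31. Besides Cyp26b1, the receptor gene Rarg fell by 0.38 on the log2 scale (SE 0.08) and the homeobox gene Meis1 fell from 72.5 ± 4.28 to 53.1 ± 3.75 CPM, while Rarres1 rose from 2.68 ± 0.840 to 6.39 ± 0.441 CPM. The adjusted p was 0.0314 for Rarg, 0.0324 for Meis1 and 0.0198 for Rarres1, and among the 6 fits without a library the call was kept in 0, 1 and 3. Without mutant replicate 2, for example, the adjusted p was 0.0747 for Rarg, 0.152 for Meis1 and 0.105 for Rarres1, and without mutant replicate 1 it was 0.108, 0.0928 and 0.0679. The calls also ended without control replicate 1 or 3 for Rarg (0.0706 and 0.0997) and Meis1 (0.0697 and 0.119), without control replicate 2 for Rarg and Rarres1 (both 0.0654), and without mutant replicate 3 for Rarg (0.126) and Meis1 (0.0667). With sex as a covariate those of Rarg and Meis1 ended (0.0616 and 0.0528). Rarb and Rara had log2 fold changes of -0.50 and -0.08 (adjusted p = 0.190 and 0.770).

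The pan-endothelial list did not pass camera, with a median of 0.03, a mean of -0.02 and a downward test (adjusted p = 0.875). Of its 26 genes, 1 rose (Robo4), 4 fell and 21 did not pass, and adjusted over the list alone 3 rose and 4 fell. The 5 called genes became 2, 3 and 0 without control replicates 1, 2 and 3, and 1, 2 and 3 without mutant replicates 1, 2 and 3. The adrenomedullin receptor gene Calcrl went from 1644 ± 111 to 699 ± 213 CPM and Tspan7 from 599.9 ± 58.1 to 435 ± 30.1 CPM, calls kept in 2 and 1 of the 6 fits without a library. Without control replicate 3 the adjusted p was 0.113 for Calcrl, 0.102 for Tspan7 and 0.0897 for Robo4, whose call was kept in 2 of these fits. The call of Calcrl also ended with no low-count filter (0.0714). Of 20 venous markers, Lyve1 rose by 0.44 and Amigo2 fell by 0.83 on the log2 scale, and adjusted over the list alone 4 rose and 2 fell. Without mutant replicate 3, 3 rose and 1 fell. The call of Lyve1 ended without control replicate 2 (adjusted p = 0.0622), mutant replicate 1 (0.0700) or mutant replicate 2 (0.0904). Lyve1 was also the 1 called gene among 12 lymphatic markers, where adjusted over the list alone 1 rose and 1 fell, as they did in DESeq2 and with no low-count filter. Among 24 Notch pathway genes, Nrarp rose by 0.65 and Numb fell by 0.40, and among 22 junction genes Jam3 rose by 0.88, Cgnl1 rose by 0.35 and Gja4 fell. Among 21 endothelial-to-mesenchymal genes, Cdh2 rose by 0.55 and Zeb2 fell by 0.40, and among 20 inflammatory activation genes Cxcl10 rose by 1.97 and Cx3cl1 fell by 0.68. Adjusted over the list alone, 1 rose and 1 fell in the Notch, mesenchymal and inflammatory lists, and 3 rose and 2 fell in the junction list. The calls of Cdh2 and Cgnl1 were kept in 0 of the 6 fits without a library, that of Zeb2 only without mutant replicate 3, that of Cx3cl1 only without control replicate 3 and that of Numb only without control replicate 1 or mutant replicate 1. Without mutant replicate 2 the adjusted p was 0.187 for Cdh2, 0.184 for Cgnl1, 0.196 for Zeb2, 0.120 for Numb, 0.164 for Cx3cl1, 0.0795 for Cxcl10 and 0.0584 for Nrarp, and without control replicate 3 that of Cxcl10 was 0.0531. With sex as a covariate the calls of Cdh2, Cgnl1, Numb and Zeb2 ended (adjusted p = 0.0850, 0.0887, 0.0560 and 0.0740). That of Zeb2 also ended with limma-voom (0.0558), that of Cdh2 with upper-quartile factors (0.0566) and no low-count filter (0.0610), and that of Cgnl1 with limma-voom, RLE factors, the filter of at least 1 CPM and abundant genes left out (0.0505, 0.0502, 0.0508 and 0.0553). With all 6 libraries camera called none of the pan-endothelial, venous, lymphatic, Notch, junction, mesenchymal and inflammatory lists. At the preset correlation it called the inflammatory list upward without control replicate 2 (median 0.26, adjusted p = 0.0195) and without mutant replicate 3 (median 0.22, adjusted p = 0.00817). With all 6 libraries this list had camera adjusted p = 0.972 at an estimated correlation of 0.36 and fry adjusted p = 0.817. The Notch list had a median of -0.02, a mean of 0.03 and an upward test. Of 25 cell division, 25 DNA replication, 24 hypoxia and glycolysis and 20 dissociation stress genes, edgeR called 0, with 0, 0, 8 and 2 at an unadjusted p under 0.05. DESeq2 called 1 of these, a stress gene, and limma-voom 0, and adjusted over the list alone 0 passed. Without control replicate 3 edgeR called 1 hypoxia gene higher. Camera called none of these 4 lists with all 6 libraries. Without control replicate 3 it called the cell division list upward, with a median of 0.25 against 0.091 (adjusted p = 1.72e-05), and the DNA replication list upward, with a median of 0.22 against 0.045 (adjusted p = 0.000394). Without mutant replicate 3 it called the hypoxia list upward, with a median of 0.19 (adjusted p = 0.0385). These 3 calls used the preset correlation. The estimated correlation was 0.86 for cell division, 0.85 for DNA replication and 0.17 for hypoxia genes. Camera with these estimates, run only with all 6 libraries, gave adjusted p = 0.972, 0.972 and 0.911. The stress list had a median of 0.02, a mean of -0.00384 and a downward test.

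Of 161 tested members of the 13 lists of markers of other cell types, 2 were called. The collagen gene Col14a1, of 20 fibroblast markers, rose from 93.4 ± 4.14 to 227 ± 21.2 CPM, and Hdc, the histidine decarboxylase gene of 8 mast cell and basophil markers, fell from 50.6 ± 3.86 to 34.2 ± 3.01 CPM. The call of Hdc ended without control replicate 1 or mutant replicate 1, 2 or 3 (adjusted p = 0.0505, 0.0555, 0.0538 and 0.0785). Camera called both lists at the preset correlation, the fibroblast list upward (median 0.20) and the mast cell list downward (median -0.48), with adjusted p = 0.0114 and 0.0332. These became adjusted p = 0.889 and adjusted p = 0.298 with an estimated correlation, and fry adjusted p was 0.449 and 0.0641. Without control replicate 3 the fibroblast and mast cell lists lost their call (camera adjusted p = 0.313 and 0.107), as they did without mutant replicate 1 (0.113 and 0.167), and the fibroblast list also without mutant replicate 2 (0.0807). The mast cell list also lost its call with the filter of at least 1 CPM (0.0773) and in the female libraries (0.127). The smooth muscle and pericyte list did not pass (median 0.19, camera adjusted p = 0.0751). It was called upward at the preset correlation with no low-count filter (0.0343), limma-voom (0.0341), and without control replicate 1 (0.0314), control replicate 2 (0.00189) or mutant replicate 3 (0.00514). With all 6 libraries its camera adjusted p was 0.972 at an estimated correlation of 0.58, and its fry adjusted p was 0.716. Adjusted over the list alone, 1 fibroblast marker rose, 1 mast cell marker fell and 3 lymphocyte markers rose. In the alveolar type 1 and type 2, airway, smooth muscle and pericyte, macrophage and monocyte, neutrophil, lymphocyte, erythroid, platelet, mesothelial and cardiomyocyte lists edgeR called 0 members. At an unadjusted p under 0.05 were 1, 0, 1, 1, 3, 0, 3, 1, 1, 0 and 1 of these members in that order. DESeq2 called 1 member each of the smooth muscle, macrophage and lymphocyte lists, and limma-voom 0. Without a library edgeR called members of 5 of these lists, namely 4 alveolar type 2 markers that fell without control replicate 3, 1 alveolar type 1 marker that rose and 1 platelet marker that fell without control replicate 1, 3 macrophage markers that rose without mutant replicate 1 and 1 lymphocyte marker that rose without mutant replicate 2. The lymphocyte list had a median of -0.02 and a mean of -0.05 with an upward test, and the airway list -0.02 and 0.12 with an upward test. Surfactant gene Sftpc, the most abundant alveolar type 2 marker, stood at 1092 ± 322 and 1052 ± 44.1 CPM (adjusted p = 0.937), and the macrophage gene Lyz2 at 437 ± 106 and 372 ± 54.1 CPM (adjusted p = 0.647). The alveolar type 2 markers varied within the controls, with list medians of log2 CPM relative to the control mean of 0.50, 0.16 and -0.69 in control replicates 1, 2 and 3, and of -0.16, -0.09 and -0.18 in mutant replicates 1, 2 and 3. Without control replicate 3 camera called this list downward, with a median of -0.46 (adjusted p = 1.64e-11), and without control replicate 1 it called the alveolar type 1 list upward, with a median of 0.33 (adjusted p = 0.0165). Both calls used the preset correlation, while the estimated correlation was 0.92 for each list. Camera with that estimate, run only with all 6 libraries, gave adjusted p = 0.972 for type 2 and 0.9997 for type 1 markers.

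Camera at the preset correlation called 10 of the 36 lists, 5 upward and 5 downward, and the estimated correlation left 0, with 5 at an unadjusted p under 0.05. When the libraries were regrouped so that each group mixed control and mutant, the preset correlation called 7 to 16 lists. The count of 10 therefore does not set the real groups apart. Some called lists share genes, so they are not separate results. Col4a1 is on the tip cell, basement membrane and TGF-beta target lists, and Gja4 on the arterial, shear stress and BMP target lists. Fry, which does not compare a list with other genes, called 6, all among the 10.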

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

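The fit on female libraries only was chosen after the data were seen, and the other alternatives before. The Smad4 level kept its direction and its call in every alternative, with log2 fold changes from -1.17 without mutant replicate 3 to -0.99 without mutant replicate 2. Against 488 genes changed, DESeq2 called 747 (445 higher, 302 lower), of which 487 were shared. In the simulated comparison DESeq2 recovered 40.3% of genes changed 1.5-fold with 32 false calls in all, against 29.9% and 11 for edgeR. What accounts for the difference in these libraries was not tested. The other settings with all 6 libraries gave 442 (limma-voom) to 565 (no low-count filter). Fits without a library have fewer samples, and gave 211 (without mutant replicate 2) to 428 (without control replicate 1) changed genes and 103 (without mutant replicate 2) to 204 (without mutant replicate 1) changed at least 2-fold. The female libraries gave 415 changed genes, 288 of them shared, and with 2 libraries per group the calls of 27 named genes ended (adjusted p = 0.0519 to 0.336), namely Acvrl1, Amigo2, Angpt2, Bbc3, Calcrl, Cdh2, Cgnl1, Clec1a, Col4a1, Cx3cl1, Esr2, Hcn4, Hdc, Hpgd, Lyve1, Meis1, Nrarp, Numb, Phlda3, Pmepa1, Rarg, Rarres1, Robo4, Tek, Tspan7, Unc5b and Zeb2. The calls of 9 named genes each ended with sex as a covariate and with no low-count filter, 8 with limma-voom and 3 with upper-quartile factors. Against 10 lists called by camera at the preset correlation of 0.01, the estimated correlation gave 0 and fry 6. A larger correlation widens the variance that camera allows for a list. The estimate was 0.79 for interferon response, 0.51 for basement membrane, 0.21 for tip cell and 0.17 for general capillary genes. It was -0.036 for the mast cell list, which also lost its call, so these estimates alone do not account for every loss. With an estimated correlation camera also takes its degrees of freedom from the few libraries, and with the preset from the many genes. These settings therefore differ in more than the correlation, and the losses cannot be read as an effect of correlation alone. The cause of the difference to fry was not tested. Of 82 called named genes other than Smad4, 41 kept their call in all 6 fits without a library, 49 in all other alternatives and 39 in every fit, and 0 changed sign. The count of called members moved by over 1.5 times in 7 (without mutant replicate 3) to 17 (without mutant replicate 2) of the 36 lists in fits without a library, in 15 in the female libraries, 7 in DESeq2, 7 with the replicate block, 4 with sex as a covariate, 3 with no low-count filter, and 1 each with limma-voom and upper-quartile factors. Among genes that were not called, the sign reversed in the female libraries for Aldh1a1 (0.066), Btg2 (-0.13), Eng (-0.012) and Sftpc (0.16). Without a library the log2 fold change ranged from -0.13 to 0.053 for Aldh1a1, -0.013 to 0.086 for Eng, -0.033 to 0.091 for Klf2, -0.27 to 0.14 for Sftpc, -0.026 to 0.35 for Btg2, -0.61 to 0.014 for Ptgs2, -0.11 to 0.25 for Col1a1, -0.074 to 0.19 for Tagln and -0.082 to 0.29 for Acta2, and the cause was not tested. The replicate numbers are not stated to pair the libraries, and correlations of deviations among so few libraries cannot decide it. These were -0.00955, 0.0194 and 0.156 for same-numbered libraries, against -0.154 to 0.119 for other pairs. Not every library correlated best with its own number. Same-numbered libraries also had the same sex by Xist and the Y-linked genes, so the replicate block carries sex as well. With the replicate block 466 genes were called (410 shared), 185 of them changed at least 2-fold, and 12 lists, among them the aerocyte and the smooth muscle and pericyte list (camera adjusted p = 0.0436 and 0.0114 at the preset correlation). There Smad6 was called (0.0352), and Cdh2, Cgnl1, Col4a1, Ifit1, Numb, Oas1a, Phlda3, Psme2, Rarg and Zeb2 were not (0.0949, 0.103, 0.0557, 0.273, 0.0691, 0.147, 0.0534, 0.0681, 0.0733 and 0.0870). The table of the whole series held the same values as the single files, so it was not run as another input. Small changes can be missed, since in data simulated with the depths, dispersions and number of these libraries edgeR recovered 29.9% of genes changed 1.5-fold, and the share of this that is due to depth was not tested.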

Other observations

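The tests on immune markers, single mutant libraries, pan-endothelial genes, stress genes and other splits of the libraries were chosen after the results they bear on were seen. Those on class I presentation, transcript length and GC content, the p53 targets not looked at before and the prostaglandin genes were set before theirs.

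Some genes known as targets of the tumor suppressor p53 were higher in the mutant libraries, a group chosen after its values were seen. Of 9 such genes looked at first, 6 rose, with a median log2 fold change of 0.77, and of 26 others 2 rose. Among the 9, Zmat3, an RNA-binding protein gene, rose by 0.92 (SE 0.12, edgeR adjusted p = 0.00279) and Ccng1, the cyclin G1 gene, by 0.63 (SE 0.09, adjusted p = 0.00463). Dglucy, Aen and Eda2r, also among the 9, had log2 fold changes of 1.07, 0.66 and 2.69. Trp53i11, with 1.86, completes the 6 that rose. It is also on the tip cell list, so it is not separate evidence for each group. Other p53 targets from both sets, named after their values were seen, did not pass, with log2 fold changes of 0.37 for Cdkn1a, 0.075 for Mdm2, 0.14 for Btg2, -0.29 for Fas and -0.31 for Rrm2b (adjusted p = 0.296, 0.800, 0.841, 0.324 and 0.211). The prostaglandin transporter gene Slco2a1, also chosen after its values were seen, went from 795 ± 72.8 to 437 ± 64.3 CPM (SD, n = 3 each, adjusted p = 0.0037), beside the fall of Hpgd. The list of 19 prostaglandin handling genes that holds both had camera p = 0.0374 (downward) at the preset correlation, p = 0.0866 with an estimated correlation and fry p = 0.0127. Without these 2 and the cyclooxygenase genes Ptgs1 and Ptgs2, which had also been looked at before, the other 15 had a median of -0.035 (quartiles -0.21 and 0.066).

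The interferon genes were higher in the mutants, with list medians relative to the control mean of 1.75, 2.84 and 2.88 in mutant replicates 1, 2 and 3. The 43 immune markers had a median log2 fold change of 0.10 (quartiles -0.21 and 0.35), which argues against a larger share of immune cells but leaves open a response within those present, and the interferon median was at least 2.43 without any 1 mutant library, which argues against a single library. The 16 class I presentation genes had list medians of 0.19, 0.81 and 0.76 in mutant replicates 1, 2 and 3 against 0.19, -0.14 and -0.15 in control replicates 1, 2 and 3, so mutant replicate 1 did not exceed control replicate 1, and a median log2 fold change of 0.59, with 2 called (Psme1 and Psme2, chosen after their values were seen), camera p = 2.34e-09 at the preset correlation, 0.101 with an estimated correlation and fry p = 0.0523. The calls of Psme1 and Psme2 ended without control replicate 2 or 3 or mutant replicate 2 or 3 (adjusted p = 0.126, 0.0856, 0.111 and 0.0692 for Psme1), and that of Psme2 with sex as a covariate (0.0528). A hypothesis is that an interferon response may extend to antigen presentation, which passed only at the preset correlation, while an effect of Cre itself, carried by the mutants alone, stays open as untested.

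The lower general capillary markers could reflect fewer endothelial cells, but 25 pan-endothelial genes outside that list had a median of 0.036 (quartiles -0.09 and 0.16). Transcript length and GC content moved the capillary median from -0.42 to -0.41, with values for 14778 of 14934 genes. A hypothesis that stays open as untested is a change of capillary cell state or share within the endothelium, which bulk RNA does not separate.

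A p53 response may underlie part of the higher p53 targets, a hypothesis for which 26 targets not looked at before had a median of 0.18 (quartiles -0.09 and 0.42), with 18 above 0 and 2 called (Phlda3 and Bbc3, chosen after their values were seen). Their camera p was 0.0012 at the preset correlation and 0.0987 with an estimated correlation, and their fry p was 0.017. The calls of Phlda3 and Bbc3 were kept only without mutant replicate 3 among the fits without a library (adjusted p = 0.136 and 0.177 without mutant replicate 2), and that of Bbc3 ended with limma-voom (0.0504). The 20 stress genes, mostly immediate early and heat shock genes, had a median of 0.019 (quartiles -0.13 and 0.10), so as a set they did not rise. This does not exclude handling stress of a kind that these genes do not report. Btg2 is on the stress list and also among the p53 targets looked at first. Cre activity in the mutants alone stays open as untested.

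The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 488 changed genes and the highest other 1, and 184 against 1 changed at least 2-fold, so in each case only the real split gave as many. Each other split mixes control and mutant libraries in both groups, so a difference between the real groups widens the spread within them and lowers the counts. The size of the gap, here and for fry, is therefore not a measure of support. For lists called by camera the real split gave 10 and the highest other 16, and 5 of the splits, the real one among them, gave 10 or more. For lists called by fry the real split gave 6 and the highest other 0, so only the real split gave as many.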
